A study of Homo sapiens with 6 samples.

How the data were processed

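Transcript levels were measured in total RNA of sorted human CD8+ effector memory T cells on Illumina HumanHT-12 v4 BeadChips, with 1 RNA sample per array. The labels give 3 populations, each with 2 arrays: cells low for both the IL-6 receptor and the IL-7 receptor, cells low for the IL-6 receptor and high for the IL-7 receptor, and cells high for both. Groups and replicate numbers were taken from the labels. These say that RNA was prepared independently within each condition but do not name separate donors, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 2 per population, limits the precision of every value.

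The values used are the authors' deposited log2 signals. BeadStudio 3.2 is named in the submitters' processing notes; the background correction and the normalization method are not given in the sources used here. All 6 columns hold the same sorted values to within 0.00164, so the signals had been quantile-normalized before deposit. They run from 6.28 to 14.74 with a median of 6.79 in each column, and most probes lie just above the lowest value, so no background appears to have been subtracted. The log base was read from that range, which as a natural log would exceed what a 16-bit scanner can record. Fold changes of dim genes are therefore compressed. A second table of signals before normalization was not used, because its 6 columns carry names that no label ties to a sample.

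The tests had been planned for scanner signals with detection p-values. Because the usable values were already normalized and carry no detection p-value, no background correction or normalization was repeated, and a background limit took the place of the detection filter. The limit is the mode of all values, 6.709, plus the normal quantile of the 99th percentile times the spread below the mode, 0.132, which gives 7.017. It was chosen after the distribution of the values had been seen and before any test was run. Probes above it on at least 2 of the 6 arrays were tested, 15775 of 47323. The platform annotation gave exactly 1 gene symbol for 30113 probes and several for 8, and 17202 probes are unnamed here, 3333 of them among those tested. A gene was represented by its brightest probe over the 6 arrays, chosen without regard to group, which left 9681 genes. Probes of XIST and of Y-linked genes were left out of every table.

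Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to all 6 arrays, which share 1 estimate of the spread with 3 residual and 4.17 prior degrees of freedom. The 3 comparisons were IL-6R high against low among IL-7R high cells, IL-7R high against low among IL-6R low cells, and the outer populations against each other. P-values were adjusted by the Benjamini-Hochberg method over all probes of a comparison, and genes with an adjusted p under 0.05 are called. Values are given with the standard error (SE) of the fit. Where every array of a group lay below the limit, the fold is given as a bound: the mean of the bright group against the mean of, per array, the higher of the limit and the measured signal. Where only 1 array of a group did, the fold is given from the measured signals, although that group's mean may lie near or below the limit. On 10 simulated sets with the measured means and spreads drawn from the fitted prior, 200 of 15775 probes were changed between IL-6R high and low cells. The fit called 68.6% of probes changed by a log2 of 1 and 97.4% of those changed by 2. On average 9.0 unchanged probes were called per set. The simulated arrays had equal spread and independent noise. The measured replicate differences had SDs of 0.197 in cells low for both receptors, 0.316 in IL-6R low IL-7R high cells and 0.337 in cells high for both. These rates may therefore not hold for the measured arrays.

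Gene lists were fixed before the data were examined: 25 lists of T cell states, receptors, pathways and markers of other cell types, of which 24 had at least 3 measured members. The 5 main lists hold early memory genes, cytotoxic effector genes, NK receptors, type 2 genes, and type 17 and MAIT cell genes (MAIT cells are mucosal-associated invariant T cells). Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, and again with the estimated correlation, with adjustment over the 72 tests; fry was run beside it. Camera called 30 of the 72 tests at the preset correlation and 0 with the estimated one, where the smallest adjusted p was 0.342 and 9 tests had an unadjusted p under 0.05. Fry called 16 for movement in 1 direction and 51 for movement in either direction.

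The genes named were chosen by a rule fixed before the data were examined: 29 key genes of the sort and of T cell differentiation, whether called or not; the 8 largest rises and the 8 largest falls among called genes whose arrays do not overlap between the groups, with open places filled by the largest moderated statistic and given as values that did not pass; and up to 4 called members per list by smallest p. Placeholder symbols and genes whose presence varies between people were left out of the largest changes. Any other list member is named with its value and was chosen after its values were seen. The alternatives covered background correction, the filter on dim probes, the probes of a gene, the variance model, array weights, the arrays in the fit, the replicate number as a block, each array left out, the threshold and the set test.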

Results

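Signals of 9681 genes were compared between 3 sorted populations of human CD8+ effector memory T cells, the antigen-experienced cytotoxic T cells that lack the homing profile of central memory cells. The populations were low for both the IL-6 receptor (IL-6R) and the IL-7 receptor (IL-7R), low for IL-6R and high for IL-7R, or high for both, with 2 arrays each. The series asks whether IL-6R marks a less differentiated part of the effector memory pool. The first principal component held 55.9% of the variance and ordered the arrays by population, at -26.54 and -25.05 for cells low for both receptors, -9.94 and -3.65 for IL-6R low IL-7R high cells, and 30.47 and 34.71 for cells high for both.

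The sorting receptors were examined first. IL7R, which encodes the alpha chain of the IL-7 receptor, was 6.05-fold higher in IL-7R high than in IL-7R low cells among IL-6R low cells (log2 change 2.60 ± 0.16 SE, adjusted p = 0.0105, n = 2 arrays per group). Its log2 signal was 13.51 ± 0.05 (SD) in IL-6R low IL-7R high cells and 13.17 ± 0.13 in cells high for both, a difference of -0.35 that was not called (adjusted p = 0.231), and the other probe of the gene differed in the opposite direction. Against cells low for both receptors, IL7R was 4.76-fold higher in cells high for both (adjusted p = 0.00210). IL6R was dim. Its 1 tested probe lay below the background limit in both IL-6R low populations and reached 7.32 ± 0.20 in IL-6R high cells. That was called against cells low for both receptors (at least 1.23-fold higher, adjusted p = 0.0344). It missed the threshold against IL-6R low IL-7R high cells (at least 1.23-fold, adjusted p = 0.0577). The other IL6R probe lay below the limit on all 6 arrays and was not tested. Its mean was 6.76 in cells low for both receptors, 6.72 in IL-6R low IL-7R high cells and 6.78 in cells high for both. IL6ST, the signalling chain shared by the IL-6 receptor family, had a log2 change of 0.47 ± 0.18 between the IL-7R high populations (adjusted p = 0.156). It had one of 0.46 between the outer populations (adjusted p = 0.118) and one of -0.01 in the IL-7R comparison.

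**Figure D1:**
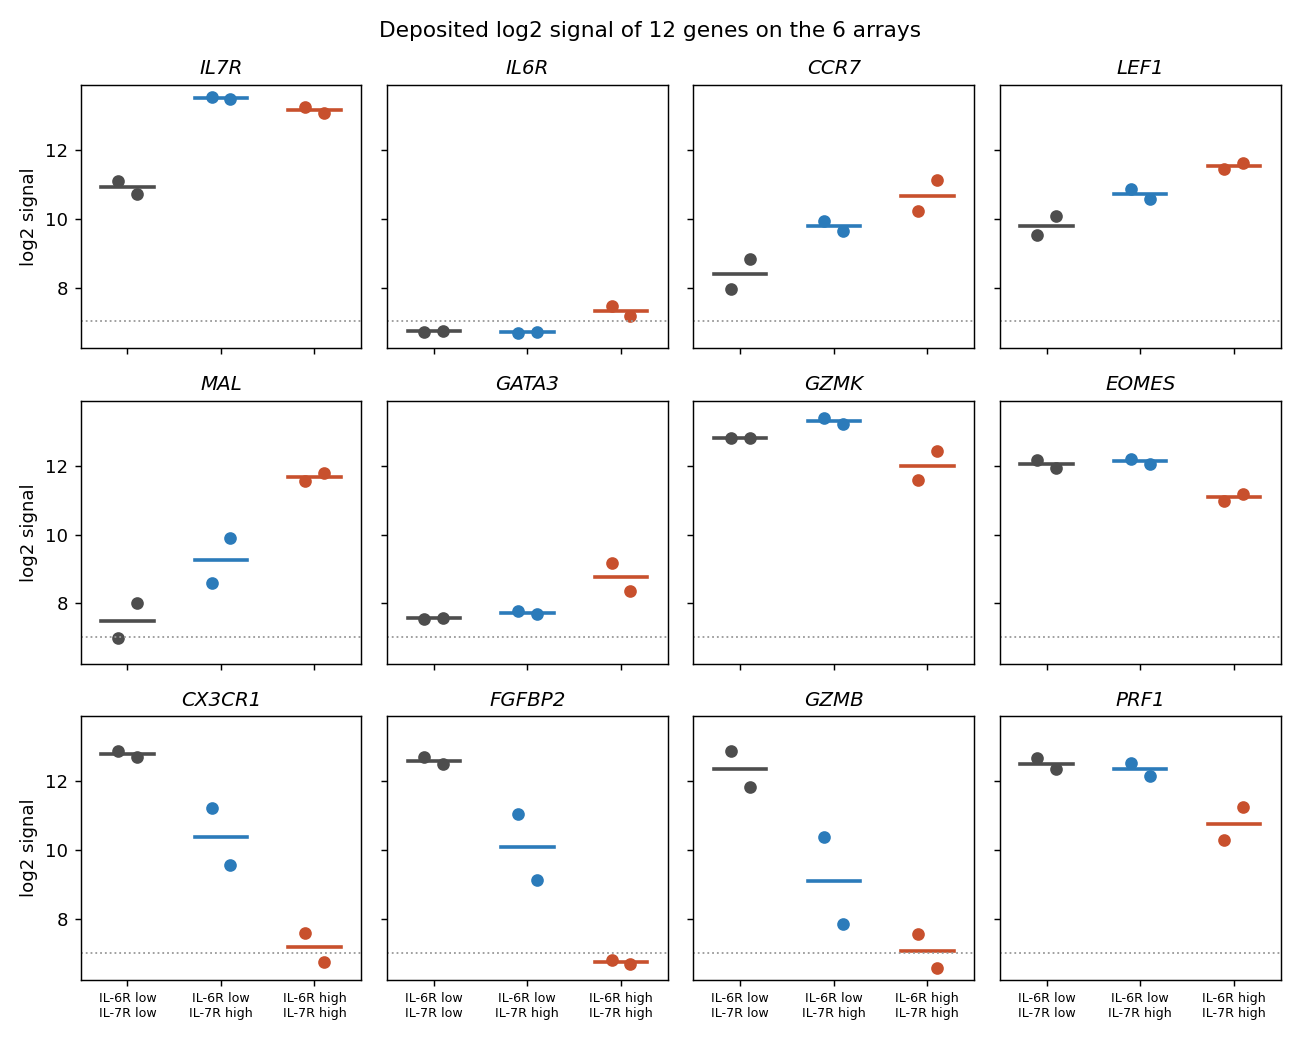
Deposited log2 signal (y axis) of 12 genes in the 3 populations (x axis); each point is 1 array, each bar the mean of 2 arrays, and the dotted line the background limit of 7.017. IL7R separates the IL-7R low population from the other 2 populations, with a mean of 10.92 against 13.51 and 13.17, and FGFBP2 has means of 12.61, 10.09 and 6.75 from the population low for both receptors to the one high for both.

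IL-6R high cells had lower signals of FGFBP2, CX3CR1, CD160 and PRF1 than IL-6R low cells when both were high for IL-7R. FGFBP2, a secreted product of cytotoxic lymphocytes, was at least 8.39-fold lower (adjusted p = 0.0314), and the fractalkine receptor CX3CR1 was 9.35-fold lower (log2 change -3.23 ± 0.50 SE, adjusted p = 0.0314). The receptor CD160 fell by 2.39 ± 0.22 on the log2 scale, the Src family kinase FGR by 2.38, and the NK receptors KLRF1 and KLRD1 fell by 1.76 and 1.75. PRF1, which encodes perforin, fell by 1.58 ± 0.30 (adjusted p = 0.0454). On the other side, HDC, the histamine-forming enzyme histidine decarboxylase, was 7.33-fold higher (log2 change 2.87 ± 0.37, adjusted p = 0.0234), and MAL, a membrane protein of T cell differentiation, was 5.36-fold higher (adjusted p = 0.0441).

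In total 325 genes were called between these populations, 212 higher and 113 lower in IL-6R high cells, and 99 of them differed at least 2-fold. The count rests on 1 spread shared by all populations. Replicates of cells low for both receptors, outside this comparison, differed less (SD 0.197) than those of the compared populations (0.316 and 0.337). The shared spread may therefore be too small here. The other largest rises were CNTNAP1, at least 6.34-fold, the formin INF2 at a log2 change of 2.39, PI16 at 2.20, GDPD5 at 2.18, PNPLA7 at 2.08 and VIPR1, a receptor for vasoactive intestinal peptide, at 1.92. ATP9A completed the largest falls, at least 2.54-fold. The naming rule required both IL-6R high arrays of these genes to lie outside the range of the IL-6R low arrays, so that separation is no further result.

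Of 34 measured cytotoxic effector genes, 9 were called lower and 0 higher. Adjusted over the list alone, 22 were lower and 2 higher. The median log2 change of the list was -1.02 (camera adjusted p = 3.03e-09, n = 34 genes; adjusted p = 0.357 with an estimated correlation). PLEK fell by 1.34, the granzyme GZMM by 1.06 and EFHD2 by 1.00. GZMB (-2.04 ± 0.78, adjusted p = 0.166), GZMH (-3.04 ± 0.71, adjusted p = 0.0659), GNLY (-1.20, adjusted p = 0.123) and KLRG1 (-1.61, adjusted p = 0.0774) had negative changes that missed the threshold. B3GAT1, which makes the CD57 epitope, lay below the limit in IL-6R high cells and was not called. The 15 measured genes of GZMK-positive, less differentiated effector memory cells had a median of -0.74 with 3 called lower and 9 adjusted over the list alone (camera adjusted p = 1.34e-05; adjusted p = 0.387 with an estimated correlation). Among these the granzyme GZMK fell by 1.28 ± 0.25 (adjusted p = 0.0483), the transcription factor EOMES by 1.05 and LYAR by 0.92. Of 20 measured NK receptor genes, 3 were called lower and 1 higher, LILRB1, whose other probe differed in the opposite direction. Over the list alone 6 were lower and 1 higher (median -0.55, camera adjusted p = 3.17e-04; adjusted p = 0.524 with an estimated correlation). Without replicate 1 of the IL-6R high population the NK receptor median was -0.22 and its test was no longer past the threshold (camera adjusted p = 0.153).

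Of 25 measured early memory genes, MAL alone was called higher. Adjusted over the list alone, 4 were higher and 1 lower (median 0.13, camera adjusted p = 0.0588; adjusted p = 0.686 with an estimated correlation). That median was 0.059 and 0.24 without replicate 1 or 2 of IL-6R low IL-7R high cells, and 0.25 and 0.066 without replicate 1 or 2 of IL-6R high cells. CCR7, a lymph node homing receptor, had a log2 change of 0.89 ± 0.36 (adjusted p = 0.185), and LEF1, a transcription factor of naive and early memory T cells, one of 0.83 ± 0.20 (adjusted p = 0.0724). The costimulatory receptors CD27 (-0.05) and CD28 (-0.01) differed by less than their SE. Of 11 measured type 2 genes, the cytokine IL10 was called higher, at 1.01 ± 0.12 (adjusted p = 0.0232). Adjusted over the list alone, 5 were higher and 3 lower. The 1 tested probe of IL10 was bright in every population. Its mean was 12.21 in IL-6R high cells, 11.20 in IL-6R low IL-7R high cells and 11.25 in cells low for both receptors. Whether that probe measures IL10 alone was not tested. The type 2 median was 0.29 and missed the threshold (camera adjusted p = 0.0501; adjusted p = 0.387 with an estimated correlation). It was 0.56 without replicate 2 of IL-6R high cells. The type 2 regulator GATA3 had a change of 1.03 ± 0.25 (adjusted p = 0.0697), IL4R one of 1.20 ± 0.33 (adjusted p = 0.0894) and the prostaglandin D2 receptor PTGDR2 was at least 2.99-fold higher, with none of the 3 called (adjusted p = 0.118 for PTGDR2). Probes of IL2, IL5 and IL13 lay below the background limit on all 6 arrays, with highest log2 signals of 6.74, 6.92 and 6.55, and IL4 was above it on 1 array. So no difference in these cytokine transcripts was detectable. Of 12 measured type 1 genes 0 were called and 5 were lower adjusted over the list alone (median -0.26, camera adjusted p = 0.0127; adjusted p = 0.342 with an estimated correlation). IFNG, the interferon gamma gene, lay below the limit in IL-6R high cells (at least 1.40-fold lower, adjusted p = 0.112). It, the transcription factor TBX21 (-0.16 ± 0.11) and TNF (-0.05 ± 0.30) were not called.

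Of the costimulatory receptors and ligands, TNFRSF4 (OX40) was 3.37-fold higher in IL-6R high cells and TNFSF14 1.78-fold, although another probe of TNFSF14 differed in the opposite direction. The 17 measured members had a median of -0.08 (2 called higher, 0 lower; 3 higher and 2 lower adjusted over the list alone). Of 17 measured inhibitory receptors, CD200R1 and LILRB1 were called higher and CD160 lower, CD200R1 by at least 3.11-fold. Their median was -0.35, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.531). In the IL-6 and STAT3 pathway, the kinase JAK1 fell by 0.98 and the sheddase ADAM10 by 0.78. The 22 members had a median of -0.11 (0 called higher and 2 lower; 3 and 3 adjusted over the list alone; camera adjusted p = 0.890). The chemokine receptor CXCR6 fell by 1.18, the prostaglandin receptor PTGER2 by 0.78, and THEMIS, a T cell signalling adaptor, by 0.75. Of 30 homing genes 3 were called lower, CX3CR1, CXCR6 and PTGER2, with 3 higher and 6 lower adjusted over the list alone (median -0.24, camera adjusted p = 0.159). CD8A had a change of -0.66 ± 0.15 (adjusted p = 0.0639) and CD8B of -0.20 ± 0.38.

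Markers of other cell types were read beside these groups. Of 8 measured monocyte and myeloid genes, CD68 (2.37-fold) and MS4A6A (at least 1.48-fold) were called higher in IL-6R high cells, and the same number adjusted over the list alone (median 0.30, camera adjusted p = 0.00520; adjusted p = 0.342 with an estimated correlation). The 3 measured red cell genes had a median of -1.14, with HBA2 called 2.20-fold lower and 3 lower adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.441 with an estimated correlation). Of 5 measured CD4 T cell markers 1 was called, TNFRSF4, also adjusted over the list alone (median 0.39, camera adjusted p = 0.115), and the CD4 probe itself stayed below the limit on every array. The naive CD8 list had 0 of 11 members called and 3 higher adjusted over the list alone (median 0.35, camera adjusted p = 0.0567), and the 3 B cell genes had 0 called by either adjustment (median 0.75, camera adjusted p = 0.741).

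The count of 325 depended on the fit. It was 4 when only the 4 arrays compared were fitted, 33 with array weights and 1176 with the replicate number as a block. Leaving out an array of cells low for both receptors gives that same 4-array fit, since its partner adds nothing to the spread. Calls also changed with the array left out of the compared populations. With limma's unadjusted p, 2441 genes lay under 0.05 in the fit to 6 arrays and 1758 in the fit to only the 4 arrays compared.

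IL-7R high cells differed from IL-7R low cells, both low for IL-6R, in the sorting marker IL7R and few other called genes. Besides IL7R, the called rises were FOS, a component of the AP-1 transcription factor (3.83-fold, log2 change 1.94 ± 0.16 SE, adjusted p = 0.0122), the adhesion molecule JAML (3.66-fold), the calcium channel subunit CACNA1I (2.84-fold), SLAMF1 (2.53-fold) and the kinase PIM1 (2.47-fold). The called falls were PRSS23 (5.76-fold, log2 change -2.53 ± 0.20), the soluble collagen receptor LAIR2 (4.70-fold), LINC01451 (2.24-fold) and PDGFRB (at least 1.84-fold). These 10 genes, 6 higher and 4 lower, were all that were called without a replicate block, and limma's unadjusted p lay under 0.05 for 1013 genes. With the replicate number as a block, which the labels tie to no shared donor, 186 were called. IFNG, GZMB, CX3CR1, B3GAT1 and KLRB1, uncalled below, were then among them.

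The 8 places of the naming rule in each direction were filled with genes that did not pass: MFGE8 at a log2 change of 1.05 (adjusted p = 0.0540), CTSA at 1.07, JAZF1 at -1.26, GFOD1 at -1.34, ASCL2 at -1.80 and SLCO4C1, at least 1.74-fold lower. GZMB had a change of -3.24 ± 0.78 (adjusted p = 0.217), CX3CR1 of -2.40 ± 0.50 (adjusted p = 0.176), IFNG, the interferon gamma gene, of -1.76 ± 0.24 (adjusted p = 0.0779), CCR7 of 1.39 ± 0.36 (adjusted p = 0.251) and LEF1 of 0.91 ± 0.20 (adjusted p = 0.184). EOMES (0.08), GATA3 (0.17), PRF1 (-0.16), KLRG1 (-0.23) and CD8A (-0.27) had small changes that were not called. The same holds for TBX21 (-0.07), TNF (0.02), CD27 (0.29) and CD8B (-0.15). B3GAT1 stood at -1.0 (adjusted p = 0.226), GNLY at -0.52, GZMK at 0.48 and CD28 at 0.58 (adjusted p = 0.338), and none passed.

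Several lists passed camera at the preset correlation although few members were called, and none passed with the estimated one. Fry did not call the cytotoxic, early memory, NK receptor and proliferation lists (adjusted p = 0.0543, 0.115, 0.133 and 0.0941). It called the common gamma chain and STAT5 list (adjusted p = 0.0279). Fry also called the IL-6 and STAT3 list, the inhibitory receptors and the type 1 list (adjusted p = 0.0153, 0.0221 and 0.0465). Cytotoxic effector genes had a median of -0.78, with 1 of 34 called lower and 19 lower adjusted over the list alone (camera adjusted p = 1.23e-13; adjusted p = 0.342 with an estimated correlation). Early memory genes had a median of 0.55, with 0 of 25 called and 12 higher adjusted over the list alone (camera adjusted p = 1.22e-08; adjusted p = 0.387 with an estimated correlation). Without replicate 2 of IL-6R low IL-7R high cells the median was 0.34. NELL2 stood at 1.55 and LTB at 1.68, both uncalled and chosen after their values were seen. NK receptors had a median of -0.62, with 0 of 20 called and 11 lower and 1 higher adjusted over the list alone (camera adjusted p = 7.00e-08; adjusted p = 0.393 with an estimated correlation). Without a filter on dim probes the NK receptor median was -0.33. The common gamma chain and STAT5 list, which holds the sorting marker IL7R, had a median of 0.53, with 2 of 15 called higher and 8 adjusted over the list alone (camera adjusted p = 5.15e-10; adjusted p = 0.342 with an estimated correlation). Proliferation genes had a median of -0.36, with 0 of 20 called and 8 lower adjusted over the list alone (camera adjusted p = 4.37e-09; adjusted p = 0.387 with an estimated correlation). Type 2 genes had a median of 0.04, with 0 of 11 called by either adjustment (camera adjusted p = 0.890).

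Further lists passed at the preset correlation. Naive CD8 genes had a median of 0.30, with 0 of 11 called and 4 higher adjusted over the list alone (camera adjusted p = 1.46e-05; adjusted p = 0.342 with an estimated correlation). IL-6 and STAT3 pathway genes had a median of 0.15, with PIM1 the 1 of 22 called, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.58e-04, and 0.342 with an estimated correlation). PIM1 is also in the common gamma chain and STAT5 list. Inhibitory receptors had a median of -0.29, with LAIR2 the 1 of 17 called and 4 lower adjusted over the list alone (camera adjusted p = 0.001; adjusted p = 0.342 with an estimated correlation). Immediate early genes had a median of 0.13, with FOS the 1 of 24 called and 6 higher adjusted over the list alone (camera adjusted p = 0.00930; adjusted p = 0.684 with an estimated correlation). Type 1 genes had a median of -0.13, with 0 of 12 called and 1 lower adjusted over the list alone (camera adjusted p = 0.0464; adjusted p = 0.387 with an estimated correlation). Ribosomal protein genes, a reference group, had a median of 0.14, with 0 of 31 called and 1 higher adjusted over the list alone (camera adjusted p = 1.59e-04; adjusted p = 0.393 with an estimated correlation). Monocyte and myeloid genes (median 0.03, camera adjusted p = 0.886) and red cell genes (median -0.52, camera adjusted p = 0.0931) had 0 called by either adjustment.

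Type 17 and MAIT cell genes had the largest positive median of the 5 main lists, 1.19, with 0 of 19 called and 10 higher adjusted over the list alone (camera adjusted p = 4.91e-11; adjusted p = 0.387 with an estimated correlation). Without replicate 2 of IL-6R low IL-7R high cells it was 0.47, and 0.64 without a filter on dim probes. CEBPD stood at 2.38 ± 0.51 (adjusted p = 0.183), COLQ at 2.14, IL18RAP at 1.99, ZBTB16, the transcription factor PLZF, at least 3.71-fold higher (adjusted p = 0.263), and KLRB1, which encodes CD161, at 1.26 ± 0.67. All but KLRB1 were chosen after their values were seen. The arrays of the IL-6R low IL-7R high population stood apart in this list: centred on the mean of all arrays, its median was -0.13 in replicate 1 and 0.98 in replicate 2. KLRB1 had log2 signals of 12.57 and 14.15. Between the IL-7R high populations the list had a median of -0.38, with 1 of 19 called lower, CXCR6, and 2 lower adjusted over the list alone (camera adjusted p = 0.0442; adjusted p = 0.692 with an estimated correlation). KLRB1 stood at -1.09 ± 0.67 there and at 0.17 between the outer populations, uncalled in both. Without replicate 2 of IL-6R low IL-7R high cells that median was 0.03 (camera adjusted p = 0.667) and without replicate 1 of IL-6R high cells it was -0.27 (camera adjusted p = 0.668), so this shift did not hold without either array. It was -1.04 without replicate 1 of IL-6R low IL-7R high cells and -0.74 without replicate 2 of IL-6R high cells.

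The 10 calls between IL-7R high and low cells depended on the fit as well. The count was 0 with only the 4 arrays compared and 80 with array weights. Leaving out an array of cells high for both receptors gives that same 4-array fit. Calls also changed with the array left out of the compared populations. In the 4-array fit limma's unadjusted p lay under 0.05 for 1284 genes.

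The outer populations, cells high for both receptors and cells low for both, differed most. The cytotoxic genes FGFBP2 (at least 48.2-fold lower), CX3CR1 (49.3-fold), GZMH (41.3-fold) and GZMB (39.0-fold, log2 change -5.29 ± 0.78 SE, adjusted p = 0.0107) had the largest falls. Replicate 2 of cells high for both lay below the background limit for CX3CR1 (6.76) and GZMB (6.58), so their folds are imprecise. MAL was 18.1-fold higher in cells high for both, CACNA1I 10.7-fold (log2 change 3.42 ± 0.12, adjusted p = 2.28e-04), HDC 9.80-fold and VIPR1 9.69-fold. The early memory genes CCR7 and LEF1 were 4.85-fold and 3.35-fold higher, IFNG was at least 4.74-fold lower, and GATA3 was 2.31-fold higher (log2 change 1.21 ± 0.25, adjusted p = 0.0261). In total 1428 genes were called, 673 higher and 755 lower in cells high for both, and 340 differed at least 2-fold.

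The remaining largest rises were INF2 at a log2 change of 2.95, AXIN2, a target of Wnt signalling, at 2.86, CRIP2 at 2.81 and CNTNAP1 at 2.78. The remaining largest falls were the adhesion receptor ADGRG1 at -4.14, FGR at -4.01, CD160 at -3.96 and PRSS23, at least 8.05-fold. Of 34 cytotoxic effector genes 24 were called lower and 1 higher, the protease CTSB. Adjusted over the list alone, 26 were lower and 1 higher (median -1.74, camera adjusted p = 1.23e-13; adjusted p = 0.342 with an estimated correlation). PRF1 fell by 1.75, GNLY, which encodes granulysin, by 1.72, KLRG1 by 1.84 and the CD57-forming enzyme B3GAT1 was at least 1.98-fold lower. PLEK fell by 2.22 and EFHD2 by 1.76. Of the GZMK-positive memory genes 5 of 15 were called lower, among them CD74 (-1.30), AOAH (-1.61) and EOMES (-0.96), while GZMK stood at -0.80 (adjusted p = 0.0776). That list had 1 higher and 7 lower adjusted over the list alone (median -0.31, camera adjusted p = 0.0149; adjusted p = 0.538 with an estimated correlation). Of 20 NK receptor genes 11 were called lower and 0 higher, and 15 lower and 1 higher adjusted over the list alone (median -1.03, camera adjusted p = 1.54e-06; adjusted p = 0.402 with an estimated correlation), among them KLRD1 (-2.98), KLRF1 (-2.51) and CD244 (-1.39). The NK receptor median was -0.59 without replicate 1 of IL-6R high cells.

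Of 25 early memory genes 10 were called higher and 1 lower, and 13 higher and 1 lower adjusted over the list alone (median 0.57, camera adjusted p = 2.65e-06; adjusted p = 0.393 with an estimated correlation). NELL2 rose by 1.62 and SATB1 by 1.18, and KLF3 was at least 1.11-fold lower. CD27 (0.24 ± 0.21) and CD28 (0.57 ± 0.18, adjusted p = 0.0765) were not called. Of 11 type 2 genes GATA3, IL4R (2.64-fold) and IL10 (1.94-fold, by the same bright probe) were called higher and NFIL3 lower. Adjusted over the list alone, 6 were higher and 3 lower (median 0.34, camera adjusted p = 0.0915, and 0.393 with an estimated correlation). Type 17 and MAIT cell genes had 2 of 19 called higher, LTK (at least 2.79-fold) and ZBTB16 (at least 4.68-fold), and 3 higher and 1 lower adjusted over the list alone (median 0.41, camera adjusted p = 0.0191; adjusted p = 0.686 with an estimated correlation). Without replicate 2 of IL-6R high cells the median was 0.36 and the test missed the threshold (camera adjusted p = 0.355). Without replicate 1 of IL-6R high cells it was 0.89.

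In the common gamma chain and STAT5 list 7 of 15 genes were called higher and 0 lower, and 10 higher and 1 lower adjusted over the list alone (median 0.88, camera adjusted p = 2.88e-05; adjusted p = 0.342 with an estimated correlation). They included the sorting marker IL7R, the cytokine signalling regulators CISH (3.03-fold) and SOCS1 (2.06-fold) and the kinase PIM1 (2.08-fold). Of 22 IL-6 and STAT3 pathway genes 6 were called higher and 4 lower, 7 and 4 adjusted over the list alone, and the median of 0.26 did not pass (camera adjusted p = 0.152). The 6 higher were the sorting marker IL6R, SOCS3 (at least 1.81-fold higher), SOCS1, CISH, PIM1 and MYC. SOCS1, CISH and PIM1 are also in the STAT5 list, and MYC is also in the immediate early list. Those calls are therefore no separate evidence for this pathway. Of 12 type 1 genes 4 were called lower and 6 adjusted over the list alone (median -0.43, camera adjusted p = 0.00190; adjusted p = 0.342 with an estimated correlation), with CCL5 at -0.94, STAT4 at -0.59 and RUNX3 at -0.57 besides IFNG. TBX21 (-0.23 ± 0.11) and TNF (-0.03 ± 0.30) were not called. Of 20 proliferation genes 8 were called lower and 14 adjusted over the list alone (median -0.48, camera adjusted p = 2.06e-05; adjusted p = 0.413 with an estimated correlation), among them STMN1 (-0.73), MCM4 (-0.76), CDC20 (at least 1.62-fold lower) and GINS2 (at least 1.47-fold lower). Of 24 immediate early genes 4 were called higher and 5 adjusted over the list alone, FOS (4.56-fold), FOSB (5.22-fold), MYC (3.58-fold) and PPP1R15A (1.76-fold), while the list's median was 0.01 (camera adjusted p = 0.177).

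CD8A was 1.91-fold lower in cells high for both receptors (log2 signal 13.02 ± 0.01 against 13.95 ± 0.07, adjusted p = 0.0144), and CD8B had a change of -0.35 ± 0.38 that was not called. The naive CD8 list had 6 of 11 members called higher, and 7 higher and 1 lower adjusted over the list alone (median 1.10, camera adjusted p = 1.92e-04; adjusted p = 0.342 with an estimated correlation). Of the monocyte and myeloid genes CD68 (2.09-fold) and MS4A6A (at least 1.48-fold) were called higher and 2 adjusted over the list alone (median 0.42, camera adjusted p = 0.0101; adjusted p = 0.342 with an estimated correlation). Of the 3 red cell genes HBA2 (3.16-fold) and HBB (3.58-fold) were called lower and 3 adjusted over the list alone (median -1.66, camera adjusted p = 0.0133; adjusted p = 0.413 with an estimated correlation). Of 5 CD4 T cell markers TNFRSF4 was called higher and CXCR5 2.16-fold lower, the same adjusted over the list alone (median 0.36, camera adjusted p = 0.368). Platelet genes (median -0.28, camera adjusted p = 0.340) and B cell genes (median 0.42, camera adjusted p = 0.715) had 0 called by either adjustment. The count of 1428 was 112 and 141 without replicate 1 or 2 of the cells low for both receptors, 856 without replicate 2 of the cells high for both, and between 1374 and 1487 without any other array. The share of higher calls was 47.1%, and 58.5% without replicate 2 of the cells high for both.

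**Figure D2:**
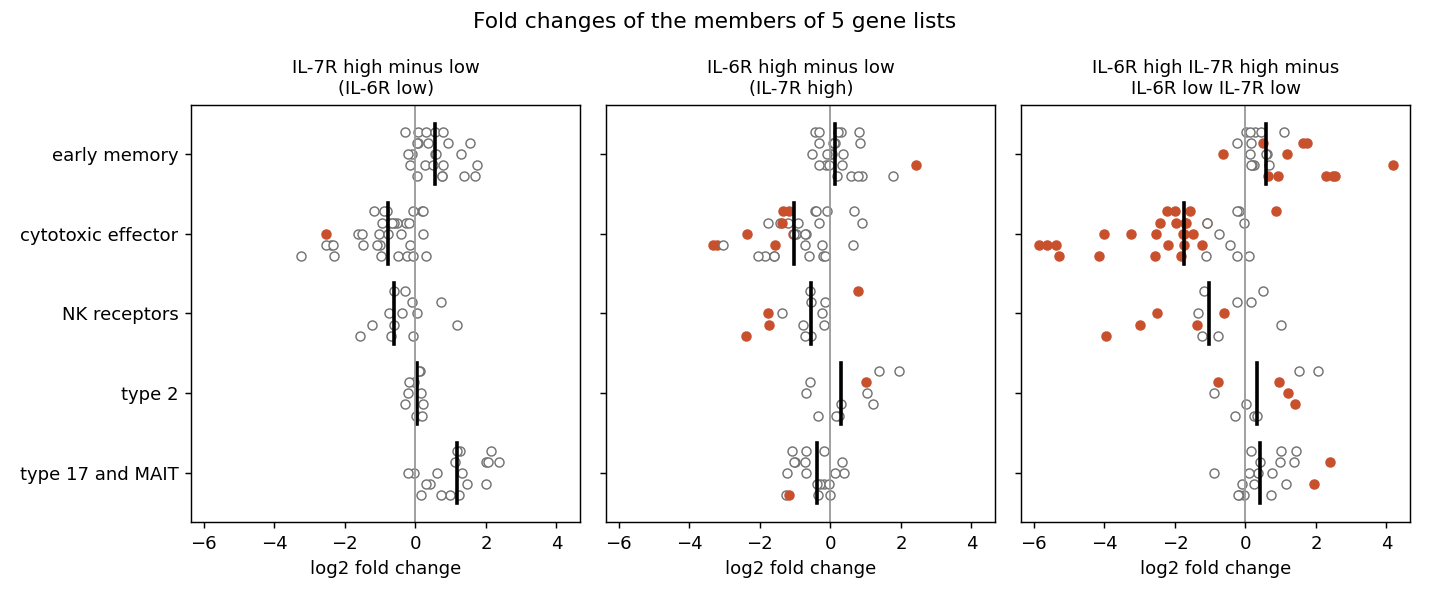
Log2 fold changes (x axis) of the members of the 5 main lists (y axis) in the 3 comparisons; each point is 1 gene, filled where called, single KIR genes are not drawn, and the bar is the median over all measured members. Cytotoxic effector genes have medians of -0.78, -1.02 and -1.74 from left to right, and type 17 and MAIT cell genes 1.19, -0.38 and 0.41.

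The IL-6R and IL-7R steps were set against each other gene by gene. Across 9681 genes, which are not independent replicates, the log2 changes of the steps correlated at 0.138. The middle population enters both with opposite sign, so the correlation without any effect was -0.500 in 100 simulations (-0.533 to -0.463). The covariance was 0.0141 against a simulated -0.0151, a difference of 0.0291. Genes were simulated as independent, with equal spread in all populations and no link between same-numbered arrays. The simulated values and their range may therefore not hold for the measured arrays. CACNA1I was the 1 gene called higher in both steps, where independent lists of 212 and 6 genes would share 0.13 and simulated lists without any effect shared 0 to 1. Of the 1428 genes called between the outer populations 1192 (83.5%) had the same sign in both steps, a share that the choice of genes by the sum of the steps favours. GZMK, which was not called between the outer populations, stood at 0.48 in the IL-7R step and fell by 1.28 in the IL-6R step. Genes higher in IL-6R high cells in the IL-6R step were also called higher between the outer populations in 198 of 212 cases and lower ones in 98 of 113. The shared IL-6R high arrays alone gave 91.4 (77 to 112) and 58.5 (49 to 70) in 100 simulations without any effect, for lists of the same sizes, and independent lists would share 14.74 and 8.81. Part of any excess may come from those arrays.

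**Figure D3:**
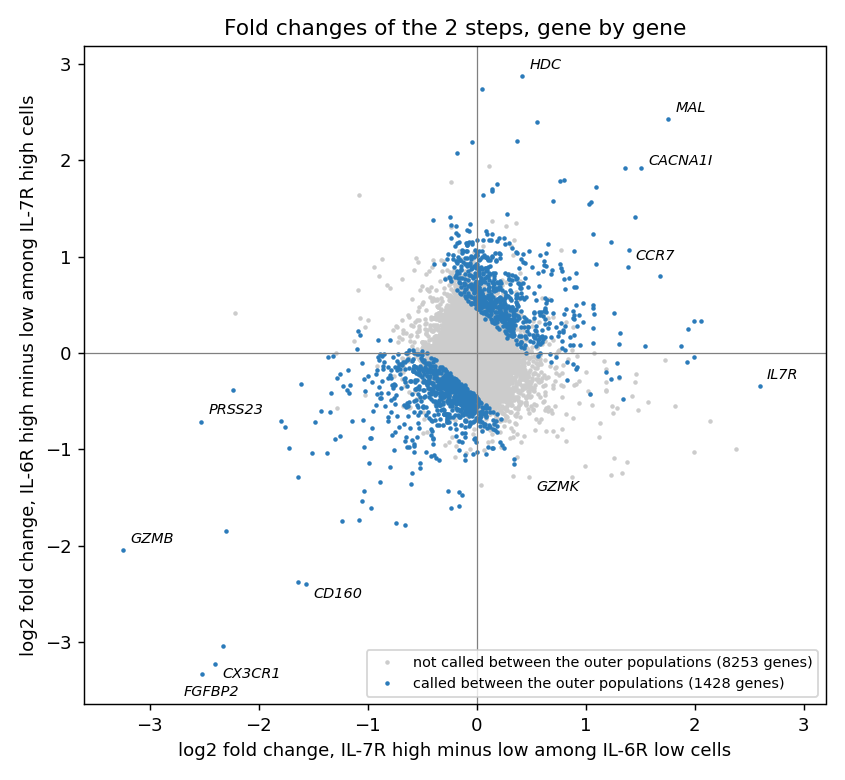
Log2 fold change of the IL-7R step (x axis) against that of the IL-6R step (y axis) for 9681 genes; blue points are the 1428 genes called between the outer populations. CX3CR1 lies at -2.40 and -3.23 and MAL at 1.76 and 2.42, while IL7R lies at 2.60 and -0.35.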

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

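The background correction with offset 16 was chosen after seeing the data; the other alternatives were planned. The planned neqc settings, median scaling and the BeadChip as a block were not run, since the usable values lack detection p-values, are already normalized and name no slide; quantile normalization without background correction and the deposited values are what was used. Signal over background limits the dim genes, IL6R and the cytokines among them. Where an array was left out its partner was assumed to vary like the other groups, and fewer arrays leave fewer residual degrees of freedom; for the other moves the cause was not tested.

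Among IL-7R high cells the 325 calls became 42 with offset 16, 33 with array weights, 4 with only the 4 arrays compared, 1027 at adjusted p under 0.1 and 99 at 2-fold, and 0 to 369 with an array left out. Among IL-6R low cells the 10 calls became 4 without a filter, 21 with trend and robust, 80 with array weights, 0 with only the 4 arrays and 34 at adjusted p under 0.1, and 0 to 46 with an array left out. Between the outer populations the 1428 calls became 2551 at adjusted p under 0.1 and 340 at 2-fold, and 112 to 1487 with an array left out. The share of higher calls among IL-7R high cells was 65.2%, 64.7% with offset 50, 71.4% with offset 16, 75.8% with array weights, 53.4% at adjusted p under 0.1, 56.1% without replicate 2 of IL-6R low IL-7R high cells and 94.3% without replicate 1 of IL-6R high cells; among IL-6R low cells it was 60%, and 50% with either offset.

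Arrays of different populations share only a replicate number, since the labels name no shared donor. Deviations of same-numbered arrays correlated at 0.557, 0.308 and 0.363. With the number as a replicate block the calls were 1176, 186 and 2547, holding all 325, 10 and 1428, and the early memory median of 0.13 among IL-7R high cells passed the threshold. The share of higher calls was then 54.4%, 51.6% and 47.3%. Under the block 23 named values that had missed the threshold passed it, among them IL6R, CD8A, IFNG, GATA3, LEF1, GZMB, GNLY, KLRG1 and KLRB1 among IL-7R high cells, IFNG, GZMB, CX3CR1, B3GAT1 and KLRB1 among IL-6R low cells, and IL6ST, CD28 and GZMK between the outer populations; 0 lost their call.

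With the estimated correlation no main list passed: the medians -1.02, -0.55 and -0.38 among IL-7R high cells (cytotoxic, NK receptor, type 17 and MAIT), 0.55, -0.78, -0.62 and 1.19 among IL-6R low cells and 0.57, -1.74, -1.03 and 0.41 between the outer populations (early memory first) lost their calls. Fry did not call -0.55 and -0.38, 0.55, -0.78, -0.62 and 1.19, nor 0.57 and 0.41. Among IL-7R high cells the early memory median gained a call with the mean of probes and with only the 4 arrays (0.13 each), and ranged from 0.059 to 0.25 with an array left out: it passed without either array of cells low for both, replicate 2 of IL-6R low IL-7R high cells or replicate 1 of IL-6R high cells, and missed without the others (adjusted p = 0.480 and 0.607). The type 2 median gained one with offset 50 (0.39), offset 16 (0.59), no filter (0.12), the looser limit (0.23), and the mean of probes, array weights and only the 4 arrays (0.29 each), was 0.15 with the limit on all 6 arrays, where the early memory median was 0.077, and ranged from 0.25 to 0.56 with an array left out, passing without any array but those of IL-6R low IL-7R high cells. The NK receptor median ranged from -0.68 to -0.22, and was -0.19 without a filter and -0.25 with the looser limit. The type 17 and MAIT median lost its call with offset 16 (-0.41) and ranged from -1.04 to 0.033, turning sign without replicate 2 of IL-6R low IL-7R high cells. Between the outer populations it lost its call without a filter (0.13) and with the limit on all 6 arrays (0.17), and ranged from 0.36 to 0.89; the type 2 median was 0.020 without a filter, ranged from 0.24 to 0.44 and passed without replicate 2 of cells high for both. The correlation of the steps, 0.138, was 0.140 with offset 50 and 0.145 with offset 16. Of 180 named values, 0 called ones changed sign, which was largely fixed in advance. Array weights, the variance model, the block and the fit to only the 4 arrays keep the differences of group means. The largest changes were also chosen among genes whose arrays do not overlap. Many named values lost their call with an array left out, most often one of the cells low for both receptors.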

Other observations

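The test of a shared source of same-numbered arrays was chosen only after the result was seen. Between the outer populations, 8 of 30 measured homing receptors and integrins were called lower and 3 higher in cells high for both receptors, and 9 and 7 adjusted over the list alone (median -0.05, limma camera adjusted p = 0.684). Besides CX3CR1 the falls included S1PR5, a sphingosine phosphate receptor of late effector cells (5.41-fold lower), and the integrin ITGAM (2.68-fold lower). Of 17 measured inhibitory receptors 7 were called lower and 1 higher, and 7 and 2 adjusted over the list alone (median -0.06, camera adjusted p = 0.0922): LAIR2 was 6.11-fold lower, CD160 15.5-fold and CD244 2.61-fold, and CD200R1 at least 3.11-fold higher. Of 17 costimulatory genes TNFRSF4 (3.83-fold), SLAMF1 (1.82-fold) and TNFSF14 (1.81-fold) were called higher and 3 lower, among them SLAMF6 (1.69-fold lower), with 5 higher and 4 lower adjusted over the list alone (median 0.06, camera adjusted p = 0.531).

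Of 21 measured T cell receptor and signalling genes 4 were called lower between the outer populations, among them CD8A, THEMIS (2.09-fold lower) and CD2 (1.71-fold lower), and PLCG1 was called 1.77-fold higher; 7 were lower and 2 higher adjusted over the list alone (median -0.18, camera adjusted p = 0.452). Interferon stimulated genes had 2 of 25 called each way, HERC5 (1.63-fold) and XAF1 (1.59-fold) higher and OASL (2.52-fold) and IFIT2 (1.86-fold) lower, and 3 higher and 2 lower adjusted over the list alone (median 0.12, camera adjusted p = 0.177). Among survival and apoptosis genes TNFSF10 was 1.98-fold higher, PMAIP1 1.92-fold lower and FASLG at least 1.82-fold lower, with 1 of 19 called higher and 3 lower, and 3 and 3 adjusted over the list alone (median 0.00, camera adjusted p = 0.890). Ribosomal protein genes, a reference group, had 1 of 31 called, RPL8 at 1.53-fold, and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.284).

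Basophils and CD4 T cells in the IL-6R high gate were weighed as a source of the genes that differed between the IL-7R high populations. Basophils, which a CD8 sort would remove and which share HDC and PTGDR2, cannot be told apart here: 0 of 7 other basophil genes were above the limit on both IL-6R high arrays with a log2 change over 0.5, but only 3 had a tested probe. These, CLC (0.42 ± 0.12), FCER1A (0.30 ± 0.29, also in the myeloid list) and IL3RA (at least 1.10-fold higher), lay near the limit and were higher but uncalled in IL-6R high cells, while CPA3, GATA2 and ENPP3 lay below the limit on every array and MS4A2 has no named probe, so the bound set beforehand decides nothing, a reading settled after the values were seen. CD4 T cells, which a CD8 sort would remove as well, cannot be told apart from the sorted cells here. The highest CD4 signal in the IL-6R high gate, 6.88, lies below the limit of 7.017, and a single dim probe decides nothing. Its mean was 6.81 in IL-6R high and 6.68 in IL-6R low IL-7R high cells. The bound set beforehand, CD4 or CD40LG not called higher, was met only in form, since neither had a tested probe. Of the other genes named beforehand CD40LG has no named probe, and CD8A (-0.66 ± 0.15) and CD8B (-0.20 ± 0.38) were not called. Naive CD8 T cells and a less differentiated memory state, which the design names, are not weighed here and stay open. Monocytes and other myeloid cells were not weighed either and stay open. Of their 8 measured genes 7 had positive changes and 1 a negative one, and CD68 and MS4A6A were called higher. Camera gave the list an adjusted p of 0.00520, and of 0.342 with an estimated correlation.

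NK cells in the IL-7R low gate were weighed as a source of the negative list medians of cytotoxic and NK receptor genes among IL-6R low cells, where 1 of 34 and 0 of 20 members were called; a CD8+ T cell sort would remove most of them. The median change of CD3D, CD3E and CD3G from IL-7R low to high cells was -0.384, but the 3 genes moved apart: CD3D (-0.38 ± 0.11) and CD3G (-0.50 ± 0.16) were brighter in the IL-7R low gate and CD3E (0.24 ± 0.16) was dimmer, and none was called. The bound fixed beforehand was not met on either part, since it needed a CD3 median within 0.2 of 0 and an NK median beyond 1: the 3 measured NK genes of the 6 chosen, all in the NK receptor list, had a median of -0.06 (KLRF1 -0.74 ± 0.29, NCAM1 -0.06 ± 0.29, TYROBP 0.04 ± 0.62). The high baseline of CD3 would hide a small share of NK cells, so such a share cannot be told apart from cytotoxic T cells that express the same genes.

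KLRB1 was higher in replicate 2 than in replicate 1 of each population, at 12.64 against 11.56 in cells low for both receptors, 14.15 against 12.57 in IL-6R low IL-7R high cells and 13.08 against 11.46 in cells high for both. A candidate source is a donor or sort shared by arrays of 1 number, with another share of MAIT-like cells, which would shift the type 17 and MAIT list in all 3 populations. The list's median difference was 0.79 and 0.51 in the IL-7R high populations, each at percentile 100 of 10000 random lists matched on level, but -0.01 in cells low for both receptors, at percentile 45.73. By the rule written for this test, a list inside the range of random lists in any population counted against a shared source. That outcome was met in cells low for both receptors. It does not exclude a shared source, because a gate low for IL-7R may hold few such cells. KLRB1 itself was higher there, but its pattern prompted the test and adds no support. From this list alone such a source and chance differences between replicates cannot be told apart. Over all tested probes, deviations of same-numbered arrays correlated positively in every pair of populations (0.557, 0.308 and 0.363). The second principal component was positive for replicate 1 (9.33, 9.39 and 20.97) and negative for replicate 2 (-4.78, -20.69 and -14.21) of each population. These values go with a shared source, which the labels do not name. The design gives no biological explanation for a difference between replicates, and no biological explanation was tested.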
